A study of Gossypium hirsutum with 6 samples.

How the data were processed

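Messenger RNA abundance was measured by RNA sequencing in leaves of upland cotton (Gossypium hirsutum), in 3 libraries of green wild-type plants and 3 libraries of virescent plants, whose young leaves are pale. Per the labels' protocols, RNA was extracted from leaves with a kit for tissue rich in polysaccharides and polyphenols. The genotype label put each library in its group. Both genotype labels are written with the same v alleles, and they differ in the MS symbol (msms for the wild type, MSms for the virescent plants); the groups are used here under the names wild type and virescent, as the labels give them. The labels number the libraries within each genotype, and nothing in them says whether the libraries came from separate plants, so the p-values measure the spread between these libraries, which may be technical.

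The authors deposited one table of FPKM values (fragments per kilobase of transcript per 1000000 mapped fragments), per the file headers, with 65126 gene identifiers and 1 column per library, rounded to 2 decimals. The aligner, the counting tool and the gene annotation are not given in the sources used here. The submitters' processing notes name only the build mm10, a mouse build, which cannot be the source of the cotton identifiers in the table. FPKM values are already divided by transcript length and by the mapped fragments of each library, so a transcript's value also moves with the share taken by the most abundant transcripts, and library sizes are unknown. Low FPKM values fall on steps set by single fragments. In genes between 0.1 and 0.5 FPKM in both libraries, the most frequent ratio of a library to wild type 1 lay between 0.988 and 1.06, an estimate of the relative worth of 1 fragment. Because the depth itself is unknown, no detection limit or counting interval is given for a gene.

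Of the identifiers, 57913 carry 1 of 26 chromosome labels of the A and D subgenomes, 1862 carry a scaffold label and 5351 have the prefix BGI_novel. No row lacked an identifier. The reference table used here, of RefSeq assembly names, matched 0 of the 65126 identifiers, and the table does not pair them with gene names. The 28 lists of pathway and cell type genes fixed before the data were examined were to be filled by product description, so 0 members were found and the planned list tests, including tests for markers of other cell types, were not run. Chromosome labels are read from the identifiers and no coordinates are given. The counting of reads from near-identical A and D copies of a gene is not described, and these copies may share reads, so single identifiers are uncertain in this respect. At least 1 scaffold identifier and 1 identifier on D05 have identical FPKM values in all 6 libraries, and both were tested. Why they are identical, and how many such pairs exist, was not examined.

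Genes with an FPKM of at least 1 in at least 3 libraries were tested, 43104 in all. Values were transformed as log2(FPKM + 1) and the genotypes were compared with limma 3.58.1 in R 4.3.3 (linear model with genotype as the only term, empirical Bayes with a mean-variance trend), with Benjamini-Hochberg adjustment and a threshold of 0.05. Genes past it are called here. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Called genes were compared between chromosome labels and between subgenomes with Fisher's exact test, two-sided, in which genes are not independent replicates. Single values per library were compared with an exact two-sided permutation test, which with 3 against 3 libraries cannot give a p below 0.1. By the rule set for a table without descriptions, the text names the 2 identifiers with the largest rise and the 2 with the largest fall among called genes whose genotypes did not overlap.

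The test was tried on simulated data with the means and spreads of the 43104 genes, in which 200 genes were changed. It recovered 64% of the 100 genes changed by 1 on the log2 scale and 100% of the 100 genes changed by 2, each in the right direction. Of its 179 calls, 15 were genes that had not been changed. The simulated noise was independent between genes and held no shift shared by a whole library. The changed genes were also far fewer than the 4459 called in the real libraries, and the Benjamini-Hochberg adjustment depends on their share. These rates may therefore not hold for the real libraries. Alternatives set before the data were examined were a pseudocount of 0.1, no filter, a filter of 5 FPKM, rescaling every library to the same sum, scaling by the median ratio to the geometric mean, no trend, the replicate number as a block, and leaving out each library in turn with the tested genes kept. Leaving out both number-2 libraries, every alternative for the correlation of the libraries, the alternatives for chromosome labels and subgenomes other than leaving out 1 library or asking for a 2-fold change, the split of calls by abundance and the tests on neighbouring identifiers were chosen after seeing the data.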

Results

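The transcriptomes of the first true leaf of a virescent cotton line and of green wild-type plants were compared, with 3 libraries per genotype. FPKM values summed to between 1019041 and 1068010 per library. Every virescent library had a higher sum than every wild-type library, at means of 1063430 and 1035870 (n = 3 per genotype, exact two-sided permutation p = 0.10, the smallest that 3 against 3 libraries allow). Between 41572 and 43109 genes reached an FPKM of 1. The number of such genes was 42036 ± 601 (SD, n = 3) in the wild type and 42751 ± 336 (SD, n = 3) in virescent leaves, a difference that missed the threshold in an exact two-sided permutation test (p = 0.30, n = 3 per genotype).

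The first question was whether the genotypes differed by more than their replicates. Across the 43104 tested genes, libraries of the same genotype correlated with a mean Pearson's r of 0.967 ± 0.0067 (SD over 6 pairs), and libraries of different genotypes with 0.928 ± 0.015 (SD over 9 pairs). These correlations are across genes, which are not independent replicates. The first principal component held 55.9% of the variance and separated the genotypes. Wild type 2 lay nearest to the virescent libraries on it, at -24.9 against -62.4 and -70.3 for the other wild-type libraries. Virescent 2 lay at 41.3, against 57.0 and 59.3.

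**Figure D1:**
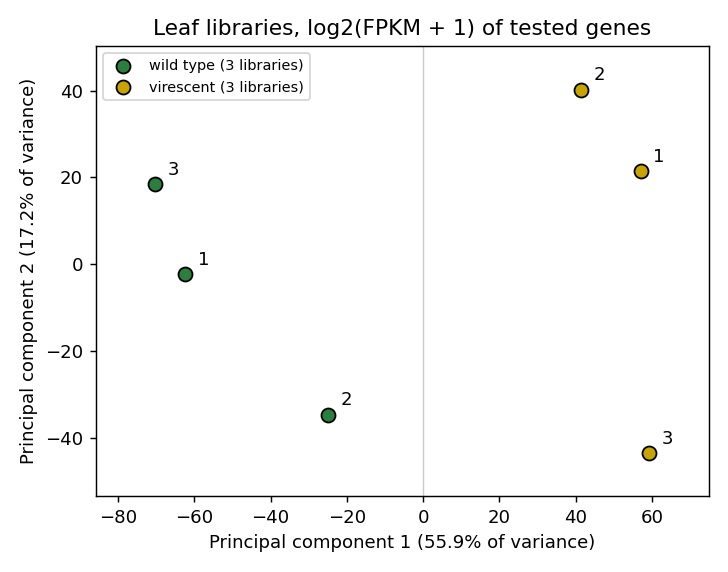
Each point is 1 leaf library, placed by the first and second principal components of log2(FPKM + 1) over the tested genes (arbitrary units), and the digits are the library numbers within a genotype. The 3 wild-type libraries lie between -70.3 and -24.9 on the first component and the 3 virescent libraries between 41.3 and 59.3.

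Virescent leaves differed from wild-type leaves in 4459 of the 43104 tested genes (10.3%), of which 2714 were higher and 1745 lower in virescent leaves (limma, adjusted p under the threshold of 0.05). Most changes were moderate, with a median size of 0.90 on the log2 scale and quartiles of 0.67 and 1.29. At least 2-fold changes were found in 1898 genes, 1038 higher and 860 lower. Changes of at least 4-fold were found in 158 genes that rose and 147 that fell, and of at least 8-fold in 26 that rose and 22 that fell. The 2 genotypes did not overlap in any of the 4459 called genes, and in 33.7% of all tested genes, where chance gives 10%. The median standard error of a gene's log2 change was 0.16.

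These counts rested strongly on single libraries. Without wild type 1 the test called 378 genes, without wild type 3 it called 929, and without wild type 2 it called 4916. Without virescent 1, 2 or 3 it called 1569, 2555 and 2705 genes. A fit with 1 library left out has less power in any case, yet these fits differed widely among themselves. The excess of rising genes was lost without virescent 2, with 1271 higher and 1284 lower. With both number-2 libraries left out, a choice made after seeing the data, 3786 genes were called, of which 1720 were higher and 2066 lower. After scaling by the median ratio 2177 genes were higher and 2049 lower, and after rescaling every library to the same sum 2308 were higher and 1881 lower. At 2-fold or more the excess of rising genes turned in more fits, with 923 higher and 943 lower after scaling by the median ratio, 1265 and 1279 without wild type 2, 780 and 910 without virescent 2, and 1146 and 1569 without both number-2 libraries.

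The largest rise was that of Gh_D02G0432, on chromosome label D02, which went from 0.377 ± 0.341 FPKM (SD, n = 3) in the wild type to 147 ± 171 FPKM (SD, n = 3) in virescent leaves. Its fitted log2 change was 5.92 ± 0.87 (SE), with a limma adjusted p of 0.01144. The virescent libraries spread widely, at 80.9, 340.2 and 18.7 FPKM, and the log2 change was 4.89 without virescent 2, 6.95 without virescent 3 and 7.62 at a pseudocount of 0.1. Gh_D10G1540, on D10, rose from 4.06 ± 0.92 to 277 ± 182 FPKM (SD, n = 3), a log2 change of 5.43 ± 0.62 (SE, limma adjusted p = 0.006289). Gh_A04G1141, on A04, fell from 92.4 ± 54.5 to 1.95 ± 2.58 FPKM (SD, n = 3), a log2 change of -5.09 ± 0.68 (SE, limma adjusted p = 0.009295). Gh_D07G0318, on D07, fell from 140.0 ± 47.6 to 4.69 ± 5.41 FPKM (SD, n = 3), a log2 change of -4.999 ± 0.587 (SE, limma adjusted p = 0.006693). The call of Gh_D02G0432 was lost without wild type 1 (limma adjusted p = 0.06092), as was that of Gh_A04G1141 (limma adjusted p = 0.05269), which also missed the threshold with the replicate number as a block (limma adjusted p = 0.0528). Without virescent 2 the rise of Gh_D10G1540, at 5.04, exceeded that of Gh_D02G0432, at 4.89. Single libraries also moved the size of the other changes. The log2 change of Gh_D10G1540 was 6.26 without virescent 3, that of Gh_A04G1141 was -5.72 without wild type 2 and -5.76 without virescent 2, and that of Gh_D07G0318 was -5.74 without virescent 2. At a pseudocount of 0.1 that of Gh_A04G1141 was -6.07. With both number-2 libraries left out the log2 changes were -6.39 for Gh_A04G1141, -5.95 for Gh_D07G0318 and 5.09 for Gh_D02G0432.

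**Figure D2:**
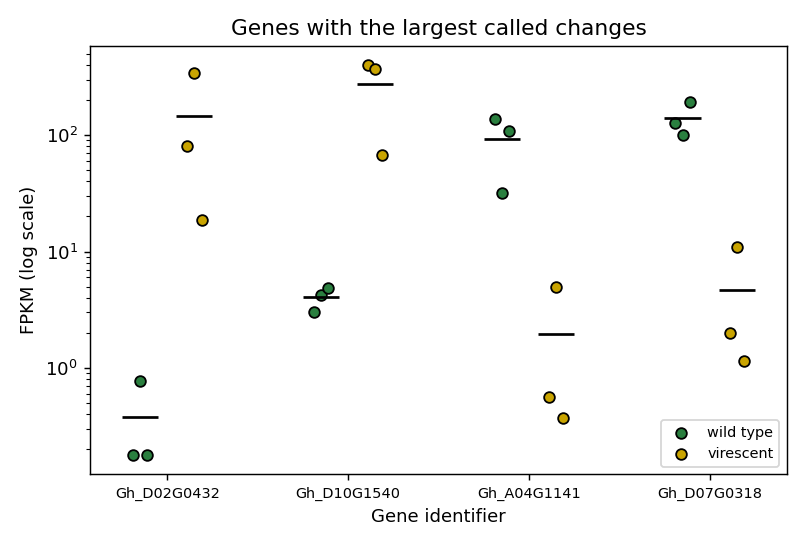
FPKM on a log scale of the 4 identifiers with the largest called changes, with 1 point per library and a bar at the mean of each genotype (3 libraries). The genotypes do not overlap in any of the 4 genes, and virescent 2 holds the highest virescent value of both genes that fell, at 4.93 and 10.9 FPKM. In both genes that rose, virescent 3 holds the lowest virescent value, at 18.7 and 67 FPKM.

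The direction of the called genes varied with transcript abundance, in classes chosen after seeing the data. The median log2 change of all tested genes also varied with abundance. It was 0.010 from 2 to below 5 FPKM, 0.151 from 100 to below 1000 FPKM and -0.069 at 1000 FPKM or more. Of the called genes with a mean of 30 FPKM or more, 580 were higher and 156 lower in virescent leaves, so that 78.8% rose (exact binomial 95% interval 75.7% to 81.7%). Below 30 FPKM, 2134 rose and 1589 fell, or 57.3% (55.7% to 58.9%). The split differed between the classes by Fisher's exact test (p = 1.69e-29), in which genes are not independent. Of the 93 genes with a mean of 1000 FPKM or more, 0 were called higher and 2 lower by limma. The most abundant transcripts thus added no rising call to this excess. With 2 calls, the share of their called genes that rises stays uncertain (exact binomial 95% interval 0% to 84.2%). The level of both shares depended on the scaling and the libraries, while the abundant class kept the higher share. After scaling by the median ratio 70.3% rose at 30 FPKM or more and 48.2% below it, and with both number-2 libraries left out 55.8% and 43.7%. With both changes together the shares were 47.8% and 36.0% (Fisher's exact test, p = 2.62e-07).

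**Figure D3:**
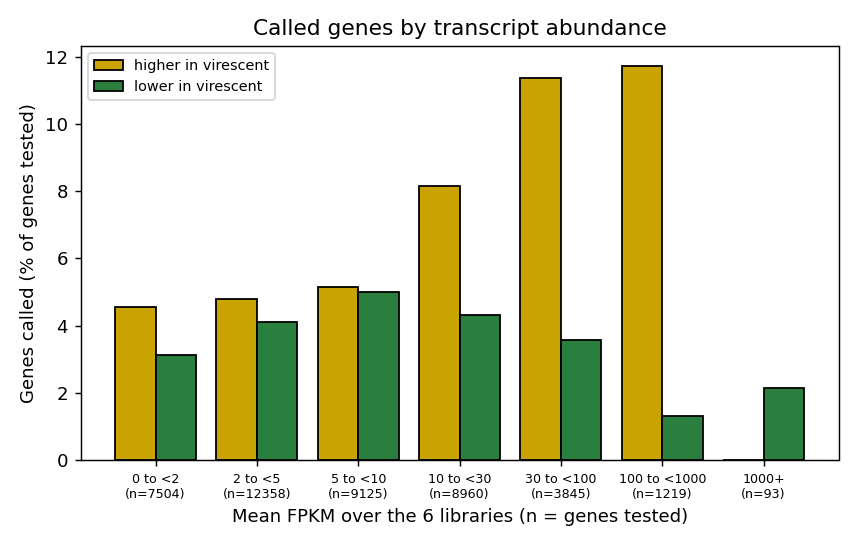
Genes called higher or lower in virescent leaves, as a percentage of the genes tested, in classes of mean FPKM over the 6 libraries. In the class from 100 to below 1000 FPKM, 143 genes were higher and 16 lower, while from 5 to below 10 FPKM 470 were higher and 456 lower.

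The 10 most abundant genes of each library held 14.3% ± 0.6 (SD, n = 3) of the summed FPKM in the wild type and 11.8% ± 0.8 (SD, n = 3) in virescent leaves. The 100 most abundant held 30.3% ± 0.4 and 26.7% ± 1.7 (SD, n = 3). All wild-type libraries lay above all virescent libraries in both shares, with p = 0.10 in the exact two-sided permutation test, the smallest p that 3 against 3 libraries allow.

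Upland cotton is an allotetraploid, with an A and a D subgenome, and the calls were compared between them. Of the 19040 tested genes with an A label, 2013 were called (10.6%), and of the 19726 with a D label, 2112 (10.7%). The odds ratio of D over A was 1.01 (95% interval 0.95 to 1.08, Fisher's exact test, p = 0.6805). In the A subgenome 1239 genes rose and 774 fell, and in the D subgenome 1286 rose and 826 fell. Called genes were spread over all 26 chromosome labels, from 9.34% of the tested genes on A12 to 12.5% on D05. No label passed the threshold in Fisher's exact test after adjustment over the labels, and the lowest adjusted p was that of D05 (unadjusted p = 0.004049, adjusted p = 0.1053). The fit without a variance trend put 1 label past the threshold.

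**Figure D4:**
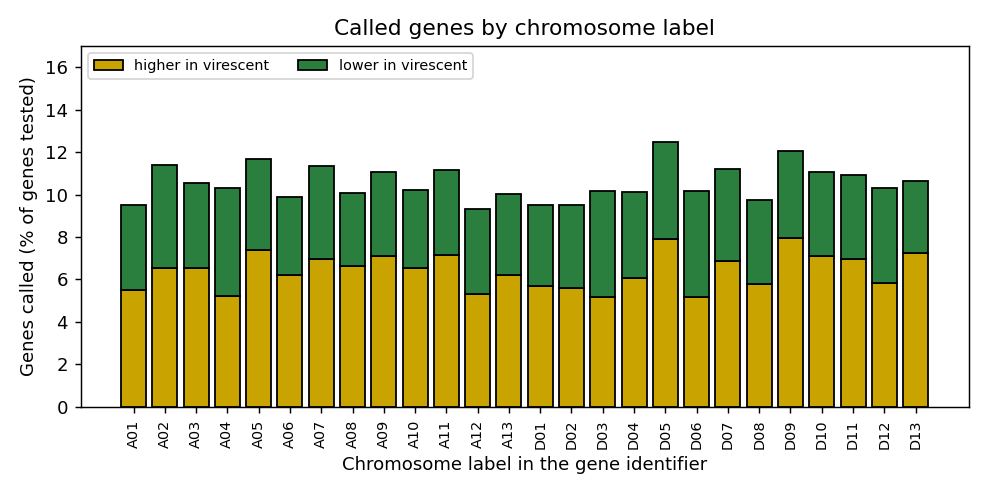
Called genes as a percentage of the genes tested for each of the 26 chromosome labels in the identifiers, stacked as genes higher and genes lower in virescent leaves. The totals run from 9.34% on A12 to 12.5% on D05, with both directions present on every label.

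Identifiers with the prefix BGI_novel were called less often than those with a chromosome label. Among 3600 tested genes with this prefix 137 rose and 111 fell (6.89% called), against 10.6% of the 38766 genes with a chromosome label (odds ratio 0.62, Fisher's exact test, p = 1.269e-13). These genes were less abundant, with a median of 2.54 FPKM against 6.07 FPKM. Of 738 tested genes on scaffolds, 86 were called (11.7%, Fisher's exact test, p = 0.3666).

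Few genes were listed in 1 genotype alone. By the rule of 0 FPKM in all 3 libraries of a genotype and at least 1 FPKM in all 3 of the other, 3 genes were listed only in virescent leaves, at 1.31 to 1.77 FPKM, and 1 only in the wild type, at 1.82 to 3.72 FPKM. The 3 genes were 1 with the prefix BGI_novel, 1 on a scaffold and 1 on A13, and the gene listed only in the wild type carried that prefix. No fold is given for them, since the other genotype is listed at 0. At a rule of 0.5 FPKM the counts were 10 and 4, and at 2 FPKM they were 0 and 0.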

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

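Without a filter on low values 2254 genes were called (1442 higher, 812 lower), and 1101 at 2-fold or more (619 and 482). The filter of 5 FPKM gave 1207 genes at 2-fold or more (643 higher, 564 lower), from fewer genes tested. The pseudocount, both rescalings and the fit without a trend kept every count of called genes within 1.5 times that reported, and every called gene tested under them kept the sign of its estimate. That sign was largely fixed beforehand, because the genotypes did not overlap in any called gene. Leaving out 1 library gave 378 to 4916 called genes (248 to 2783 higher, 130 to 2133 lower) and 359 to 2544 at 2-fold or more (232 to 1265 higher, 127 to 1279 lower), with wild type 1 behind each lowest and wild type 2 behind each highest count. Both number-2 libraries left out, tried after seeing the data, gave 1720 higher and 2066 lower, and 1146 higher and 1569 lower at 2-fold or more. The cause of these differences was not tested, and a fit with fewer libraries has less power in any case. With the replicate number as a block 665 genes were called (473 higher, 192 lower), and 629 at 2-fold or more (444 and 185). The added block terms leave less information on the spread within groups, which by itself lowers the power of the test. Deviations of same-numbered libraries correlated at 0.08, -0.28 and -0.24, and only number 1 correlated best with its own number. These values cannot show whether same-numbered libraries share more than a number. Opposite shifts of the number-2 libraries would themselves give a negative value. The odds ratio of D over A was 0.998 to 1.10 over the libraries left out, and 0.996 without a filter, always short of the threshold; 1 chromosome label passed it without the trend. The no-filter and no-trend fits of this comparison, and the correlations that follow, were added after seeing the data. Genes listed only in virescent leaves numbered 10 at 0.5 FPKM, 0 at 2 FPKM and 4 to 17 with a library left out, and those listed only in the wild type 4, 0 and 3 to 18, since fewer libraries had to meet the rule. The mean correlation within and between genotypes was 0.951 and 0.904 at a pseudocount of 0.1, 0.976 and 0.955 without a filter, and 0.900 between genotypes at 5 FPKM. The share of called genes of 30 FPKM or more that rose turned to 47.8%, against 36.0% below 30 FPKM, with both number-2 libraries left out and median-ratio scaling; the difference between these classes stayed between 11.7 and 23.8 percentage points in every fit run. The 4 named genes kept their direction in all 56 refits, which their choice among genes without overlap largely fixed beforehand. In 3 refits the threshold was missed, namely by Gh_D02G0432 without wild type 1 and by Gh_A04G1141 without wild type 1 and under the block. The depth of the libraries is unknown, so limits by depth cannot be given.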

Other observations

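Called genes with consecutive numbers in their identifiers tended to share a direction. Among 24105 pairs of tested genes with the same chromosome label and consecutive numbers, both members rose in 189 and both fell in 78, while 89 pairs went opposite ways. With calls permuted 1000 times within chromosome label and 10 classes of mean expression, 106 pairs that rose together, 41.2 that fell together and 130 opposite pairs were expected. All tests in this part other than those of the splits of the libraries were chosen after the results were seen.

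The excess of same-direction neighbours was 267 pairs against 147 expected, a ratio of 1.82, and no permutation gave more than 187 (permutation p = 0.001, the smallest that 1000 permutations can give). Like expression levels of neighbours, held fixed in these permutations, therefore do not account for it. At number distances of 20 to 50 the ratio was 1.001, with 4152 pairs observed and 4017 to 4271 in the central 95% of permutations. Over all chromosome labels together, no excess was thus seen at these distances. The pooled count could hide a few long stretches that differ between the genotypes, or stretches whose genes change both ways. It therefore cannot decide on long stretches. Joint regulation of adjacent genes, and reads shared between near-identical neighbours, stay open as hypotheses, and the identifiers are only assumed to be numbered along the chromosome.

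Wild type 2 and virescent 2 both lay toward the other genotype. The displacement of a library was measured only in genes higher in the other genotype. These reached 10 FPKM in every library of the other genotype, at least 2-fold above all remaining libraries of its own. In them wild type 2 was displaced by a median of 15.6% of the distance at 2- to 4-fold (298 genes) and 8.61% at 4-fold or more (60 genes). Virescent 2 was displaced by 20.8% (185 genes) and 15.9% (67 genes). The other 4 libraries lay between -9.96% and -0.212%. RNA of the other genotype mixed in at 1 share should displace both classes alike, and the classes differed by 6.94 percentage points in wild type 2 (95% bootstrap interval over genes 0.94 to 11.8) and by 4.84 in virescent 2 (2.46 to 8.78). With a 10% share mixed in by simulation, the interval included 0 for wild type 2 (-2.47 to 2.20) and virescent 2 (-1.61 to 3.98). That simulation had independent noise in each gene. Mixing stays open all the same, since the interval over genes does not cover the spread between libraries. The remaining libraries cannot gauge that spread. Each was measured against a reference that includes the displaced library of its genotype, which pushes its values the opposite way. Their class differences were -3.31 points in wild type 3 (-5.21 to -0.52) and -5.15 in virescent 3 (-8.27 to -2.82). They were -1.21 in wild type 1 (-2.50 to 0.085) and -1.58 in virescent 1 (-6.34 to 1.61). Exchanged labels are argued against, since the lowest correlation of either library with its own genotype exceeded its highest with the other by at least 0.0139. Differences between the plants sampled, such as leaf stage, may also place libraries along the same axis and were not tested.

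Called genes of 30 FPKM or more rose more often than those below, by 21.5 percentage points (78.8% against 57.3%). The smaller share of the most abundant transcripts in virescent leaves, which lifts all other FPKM values, is argued against as the whole cause, since median-ratio scaling left a difference of 22.2 points, with 70.3% of the abundant class rising (66.6% to 73.8%). Leaving out wild type 2 and virescent 2 lowered both classes, to 55.8% (51.5% to 59.9%) and 43.7%, and left a difference of 12.1 points (Fisher's exact test, p = 1.37e-07), so the level of the shares may come from these libraries while they do not account for the whole difference. Genes are not independent in these tests, and no biological explanation was tested.

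Every split of the 6 libraries into 3 and 3 was also fitted. The real split called 4459 genes and the highest of the other 9 called 4. At 2-fold or more the counts were 1898 and 4. Only 1 of the 10 splits, the real one, gave counts as large, in both cases, and 10 splits are too few for a share under 0.05. Each of the other 9 also had both genotypes in each group. The genotype difference then widened the spread within groups, so low counts in these splits follow from the design.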
